A study of Homo sapiens with 6 samples.

How the data were processed

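RNA immunoprecipitation was performed in MDA-MB-231, a human breast cancer cell line of the triple-negative type, with an antibody against PD-L1 or with an IgG isotype control. PD-L1, encoded by CD274, is a membrane protein best known as the ligand of the immune receptor PD-1. In this assay an antibody pulls a protein out of a cell lysate and the RNA that comes down with it is sequenced. The isotype control carries no specificity for the protein and measures the RNA that sticks to antibody and beads. Per the labels' protocols, cells were crosslinked with formaldehyde, lysed and sonicated, and the washed precipitates were made into stranded, paired-end total RNA libraries. The 6 libraries fall into 3 PD-L1 repeats and 3 IgG repeats, as the labels name them. The labels do not say whether the repeats came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

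The submitters' processing notes name TopHat2 2.0.14, HOMER 4.8.3 and genome build hg19, without giving their roles. Per the file headers, the authors' main table gives for each RNA and library a score, the sum of the scores of the peaks assigned to that gene. Peak calling settings, the number and length of peaks behind each sum and the number of reads per library are not given in the sources used here. Per the series' design text, an RNA was kept by the authors where PD-L1 was at least 5-fold above IgG. The table was therefore selected on these same libraries and for 1 direction, and tests on it are no independent evidence that an RNA was enriched. A score of 0 means that no peak was scored, not that no read was found. The deposited material also holds the authors' own Gene Ontology (GO) enrichment table, with gene counts, a fold and a p-value per term, and the authors' list of 207 DNA damage genes. The test, background and correction behind the deposited p-values are not given in the sources used here, and these values were copied and not recomputed.

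The planned tests named counts or normalised expression values. The table holds scores, so limma, planned for normalised values, was applied to log2(score + 1) and no test for read counts was run. Scores below 10 were whole multiples of a step that was constant within a library, with a tolerance of 0.015. Higher scores were not checked in this way. The step was 0.202 and 0.181 in PD-L1 repeats 1 and 2, 0.177 in repeat 3, 0.302 in IgG repeat 1 and 0.257 in both other IgG repeats. If a step is the score of 1 read, it falls as the library grows. The scores were used as the authors scaled them, since centring a table selected for 1 direction removes the enrichment common to all its RNAs. Group differences were fitted with limma 3.58.1 in R 4.3.3 and adjusted by the Benjamini-Hochberg method over the 3152 listed RNAs, at a threshold of 0.05. Values of log2 are on the log2(score + 1) scale, which understates the change of RNAs with low scores. No fold is given for an RNA at 0 in all 3 IgG libraries.

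Before the data were examined, 22 gene lists were fixed. Of these, 8 covered DNA damage signalling and repair, namely DNA damage signalling kinases and checkpoint, homologous recombination, Fanconi anaemia, non-homologous end joining, nucleotide excision repair, base excision and single-strand break repair, mismatch repair and translesion synthesis. The others were RNA exosome and nuclear decay, cell cycle and mitosis, chromatin regulators, cytosolic ribosomal proteins, oxidative phosphorylation, histone genes, nuclear and small non-coding RNAs, interferon response and antigen presentation, immune checkpoint and PD-L1 partners, mesenchymal breast cancer cell markers, epithelial cell markers, immune cell markers, neuronal and muscle markers, and membrane and secreted protein signalling. In all, 6 list entries matched no gene. For the 12 lists with 5 or more members in the table, the mean log2 difference of the members was compared with that of the other listed RNAs in a 2-sided permutation test (100000 resamples of RNAs), with Benjamini-Hochberg adjustment over these lists. Such a test describes these libraries, since RNAs and not samples are permuted. The authors' DNA damage list was tested in the same way. All 207 of its entries matched the table, 3 of them by the first of a pair of symbols. Presence in the table could not be tested, because the RNAs that failed the authors' criterion were not analysed here.

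The RNAs named were also fixed by rule. They are the 10 with the largest log2 difference among those with a mean PD-L1 score at or above the median of 31.2 and with all 3 PD-L1 scores above all 3 IgG scores, the 5 with the highest mean PD-L1 score, and up to 3 members with the largest log2 difference in each list with 3 or more members present. CD274, ATM, BRCA1, FANCL and NBN were named whatever their values, as was the RNA with the smallest log2 difference. The 10 GO terms with the smallest p-value in the authors' table complete the rule. RNAs named outside it are said to be so, and some RNAs that the rule takes are not reported here.

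Gene identifiers were matched to an NCBI RefSeq gene table of a newer assembly for gene types only, and 3147 of 3152 matched. Exon number, transcript length and GC content were taken from the longest coding transcript of each gene in GENCODE release 29, available for 3129 RNAs (99.3%). The files use hg19 and the references a newer build, so no coordinates are given. Alternatives covered pseudocounts of 0.1 and 0.01, a minimum mean PD-L1 score of 1, the repeat number as a block, rescaling of each library to the same sum over the listed RNAs, a mean-variance trend in limma, other fold criteria, medians in place of means, matching on PD-L1 score in 20 bins, and each library left out in turn. After the data were seen, 4 were added: a score of 0 set to the smallest score listed for its library, matching on exon number in 10 bins, a pseudocount of 1 in the 5-fold count, and the exosome list without MPP6.

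The limma step was tested on simulated data for 3152 RNAs of which 200 were changed. It recovered 0% of changes of log2 1, 28.0% of changes of log2 2 (59 calls, 3 of them false) and 74.0% of changes of log2 4 (154 calls, 6 of them false). The simulated noise was normal around the overall mean of each RNA. In the real table nearly all RNAs differ in the same direction and many are at 0 with IgG, so these rates do not describe the main fit. The permutation test, run on 200 random lists of 20 RNAs, called 4.0% without a shift and 99.5% with a shift of log2 1, at an unadjusted p under 0.05. Apart from homologous recombination, with 21, the fixed lists tested held only 5 to 14 RNAs, and their p-values were adjusted. The rate of 99.5% therefore does not describe these smaller lists, and a list that did not pass may still differ. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.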

Results

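The data describe which RNAs came down with PD-L1 in MDA-MB-231 cells, in 3 PD-L1 precipitations and 3 IgG isotype precipitations. The authors' table lists 3152 RNAs with a sum of peak scores per library. The summed scores of the listed RNAs were 206525 and 217732 in PD-L1 repeats 1 and 2, 123921 in PD-L1 repeat 3, and 8353, 19288 and 18823 in IgG repeats 1 to 3. These sums cover a selected list and are not sequencing depth, which is unknown, so no counting interval is given.

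The main comparison asks how far each listed RNA stood above the isotype control. Nearly all listed RNAs, 3126, come from protein-coding genes, and 13 are long non-coding RNAs. The highest PD-L1 score belonged to TRIO, a guanine nucleotide exchange factor, at 966 ± 63.2 (SD, n = 3) against 149.8 ± 24.5 with IgG. The GTPase regulators ARHGAP29 (840.4 ± 254.8 against 85.1 ± 17.6) and ARHGEF28 (693 ± 165 against 91.3 ± 9.49), the DNA damage kinase ATM (833 ± 674 against 27.0 ± 19.6) and CEP95 (691 ± 292 against 94.4 ± 21.6) completed the 5 highest. Among RNAs at 0 in all 3 IgG libraries, the motor protein RNA DYNC2H1, encoding a dynein heavy chain of intraflagellar transport, reached 344 ± 246 and FGL2, encoding a fibrinogen-like secreted protein, 189 ± 18.6. DNAH11, an axonemal dynein (181 ± 74.5), CSPP1, a centrosome and cilium protein (157 ± 40.5), PTBP2, a splicing regulator (152 ± 29.1), KIF27, a kinesin (142 ± 34.2), ADAMTS6, a secreted metalloprotease (127 ± 9.18), and TEKT2, a ciliary tektin (119.5 ± 27.9), were likewise listed at 0 with IgG.

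A total of 1000 RNAs (31.7%) were at 0 in all 3 IgG libraries. In the remaining 2152 the ratio of group means had a median of 10.5 and ranged from 5.01 to 253, the highest for PURG, a purine-rich element binding protein, at 195 ± 31.3 with PD-L1 and scores of 0, 2.31 and 0 with IgG. POLQ, the polymerase of theta-mediated end joining, followed the same form at 189 ± 68.9 with PD-L1 and 0, 0 and 2.57 with IgG. All 3 PD-L1 scores exceeded all 3 IgG scores in 3023 RNAs (95.9%). Chance gives complete separation in either direction together in 10% of unselected RNAs, a share that does not apply to a table selected on these libraries. In limma with Benjamini-Hochberg adjustment 3078 RNAs were higher with PD-L1, 74 did not pass and 0 were lower, and 0 were lower at an unadjusted p under 0.05 as well. The median log2 difference was 3.42 (quartiles 2.82 and 4.23), and 2.94 with scores of 0 set to the smallest listed score. The direction is set by the authors' selection. With each library rescaled to the same sum over the listed RNAs the median fell by 1.66 on the log2 scale and the split became 990 higher and 60 lower, against 3078 and 0. With that scaling 25 of the 55 named RNAs that had passed no longer did, and TRIO, ARHGAP29, ARHGEF28, CEP95 and POLB were lower with PD-L1 without passing the threshold.

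**Figure D1:**
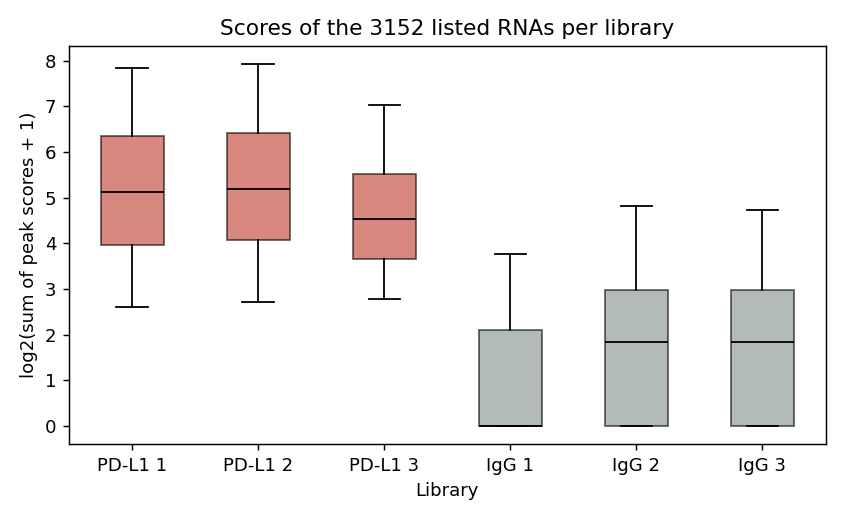
Box plots of log2(sum of peak scores + 1) for the 3152 listed RNAs in each library, with boxes from the lower to the upper quartile, lines at the median and whiskers from the 5th to the 95th percentile. The 3 PD-L1 libraries (red) have medians of 33.7, 35.5 and 22.1 on the score scale, against 0, 2.57 and 2.57 in the 3 IgG libraries (grey), under the authors' scaling and selection.

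PD-L1 repeat 3 stood apart from repeats 1 and 2, as for ATM, whose score was 57.2 in repeat 3 against 1177 and 1266 in the others. Repeat 3 was below both others in 2010 RNAs (63.8%) and above both in 754. DYNC2H1 (60.4 against 471 and 502), ATR (21.4 against 239 and 242) and POLB (5.13 against 143 and 161) showed the same order, while TRIO (1011 against 993 and 894) and ADAMTS6 (133 against 116 and 130.4) did not. Across RNAs, which are not independent replicates, the Spearman correlation was 0.969 between PD-L1 repeats 1 and 2 and 0.746 and 0.741 between these and repeat 3. Between IgG repeats it was 0.623 to 0.740. PD-L1 repeats 1 and 2 had the same score above 0 in 3 of the 3152 RNAs, and they were kept as the separate samples that the labels name. A chi-square with scores read as steps averaged 5.26 per RNA between PD-L1 repeats 1 and 2, against 4.89 to 6.09 between IgG repeats and 50.4 and 54.2 with PD-L1 repeat 3. Scores of 10 or more were not checked to be whole steps, so the chi-square does not show whether repeats 1 and 2 differ beyond counting noise. The smallest score in PD-L1 repeat 3 was 3.72, equal to 21 steps, against 10 steps in each of the other PD-L1 repeats, and 0 of its RNAs were at 0 against 24 and 19.

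The next comparison concerns the RNAs of DNA damage genes. All 207 RNAs on the authors' list were in the table, ATM, BRCA1, FANCL and NBN among them, and 203 were higher with PD-L1 (limma with Benjamini-Hochberg adjustment), as were 203 when adjusted over the list alone. The list was drawn from these samples and is not independent evidence of its direction. FANCL, the ubiquitin ligase subunit of the Fanconi anaemia core complex, scored 98.8 ± 7.09 with PD-L1 and was at 0 in all 3 IgG libraries. BRCA1, a ubiquitin ligase of homologous recombination, scored 24.4, 27.9 and 6.20 and was also at 0 with IgG. NBN, a subunit of the MRE11 complex that senses double-strand breaks, scored 41.5 ± 15.5 with PD-L1 and 0, 3.60 and 5.40 with IgG, a log2 difference of 3.72 ± 0.76 (SE), which did not pass with rescaled libraries (1.48, adjusted p = 0.455 in limma) or with a pseudocount of 0.01 (6.10, 0.0828). ATM differed by log2 4.25 ± 1.33 (SE) with an adjusted p of 0.0199 in limma. With rescaled libraries it fell to 0.71 (adjusted p = 0.652 in limma). It also did not pass without PD-L1 repeat 1 (3.55, adjusted p = 0.0851 in limma), PD-L1 repeat 2 (3.49, 0.0849) or IgG repeat 1 (3.67, 0.0546), and the lowest adjusted p over all alternatives was 0.00374.

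Members of the authors' list and the other 2945 listed RNAs had mean log2 differences of 3.72 and 3.59. The difference of 0.14 did not pass the threshold (permutation test, p = 0.0615), though it did without PD-L1 repeat 3 (0.19, permutation p = 0.0173), without IgG repeat 2 (0.17, permutation p = 0.0302) and with scores of 0 set to the smallest listed score (0.24, permutation p = 0.00056). It was negative with the rescaled libraries, at -0.06, and over all alternatives the permutation p reached 0.64. The share at 0 in all 3 IgG libraries was 29% on the list and 31.9% off it. Members had a median of 15 exons against 11, and a median mean PD-L1 score of 45.7 against 30.4. Of 162 genes on the 8 fixed repair lists 74 were in the table, and 72 of these were on the authors' list. The others were the helicase-nuclease DNA2 and the checkpoint kinase WEE1, named after their values were seen.

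**Figure D2:**
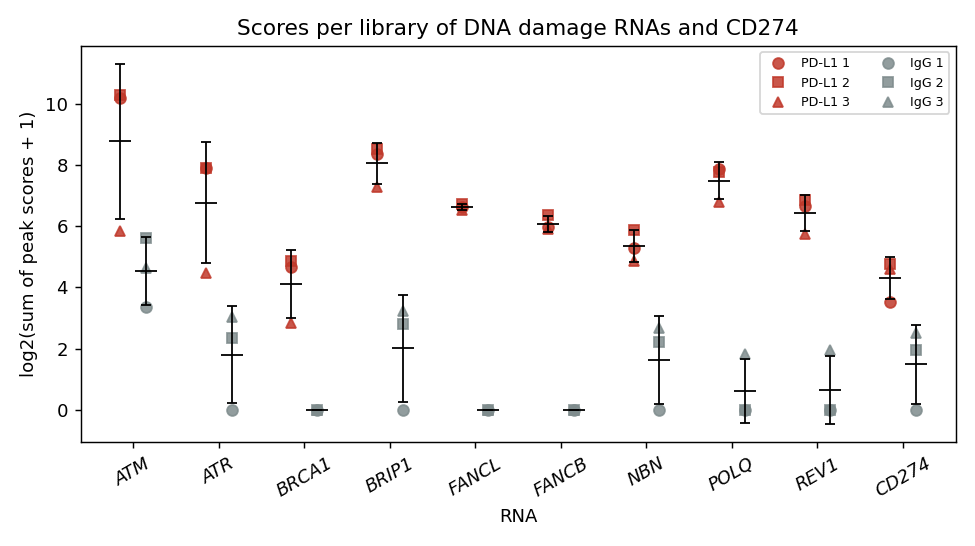
Scores per library, as log2(sum of peak scores + 1), for 9 RNAs of DNA damage genes and CD274, with PD-L1 in red, IgG in grey, a symbol for each repeat, and the mean and SD of each group of 3 in black. In each RNA the 3 PD-L1 scores lie above the 3 IgG scores, and the ATM score of PD-L1 repeat 3 (57.2) lies near that of IgG repeat 2 (48.1).

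The fixed repair lists differed in how far their RNAs stood above the others. The 8 listed translesion synthesis RNAs, whose products copy past damaged bases, had the largest enrichment, with a median log2 difference of 5.25 and a mean 1.65 above the other listed RNAs (permutation test, adjusted p = 0.00036). They were led by POLQ, the ubiquitin ligase RNA SHPRH (165 ± 93.7 against 0, 2.31 and 0) and REV1, a Y-family polymerase (90.3 ± 33.1 against 0, 0 and 2.83). The 11 Fanconi anaemia RNAs, of the pathway that repairs DNA interstrand crosslinks, had a median of 5.11 and a mean 1.05 above the others (permutation test, adjusted p = 0.00576). FANCL, FANCB (68.0 ± 13.0, at 0 with IgG) and the helicase BRIP1 (286 ± 113 against 0, 5.92 and 8.48) led them. With rescaled libraries BRIP1 did not pass (log2 difference 3.74 against 6.06, adjusted p = 0.134 in limma). All 8 and all 11 were higher with PD-L1, also adjusted over the list alone, as were 3078 of all 3152 listed RNAs. In a table selected for this direction such counts, here and below, do not set a list apart. With scores of 0 set to the smallest listed score the medians of the 2 lists were 4.57 and 4.47, against 2.94 over the table. With a pseudocount of 0.01 the differences were larger, at 2.67 and 1.98, but so was the SD of the log2 difference over all listed RNAs (3.07 against 1.02), and neither list passed. The adjusted permutation p-values were then 0.0712 and 0.0937, the highest over all alternatives, against lowest values of 0.00024 and 0.00072.

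All 21 listed homologous recombination RNAs were higher with PD-L1, also adjusted over the list alone, with a median log2 difference of 4.13, among them GEN1, a Holliday junction resolvase (111 ± 23.2, at 0 with IgG), and EXO1, an end resection nuclease (56.0 ± 19.1, at 0 with IgG). Their mean lay 0.52 above the other RNAs, which did not pass after adjustment (permutation test, p = 0.0181, adjusted p = 0.0724) but did without PD-L1 repeat 3 (0.63, adjusted permutation p = 0.0419, in a range to 0.519 over all alternatives). Non-homologous end joining had 9 RNAs, 8 of them higher, with a median of 3.91, and besides POLQ was led by APLF (50.6 ± 7.88) and DCLRE1C, the Artemis nuclease (22.4 ± 14.3), both at 0 with IgG. Its remaining RNA, C9orf142, encodes the end joining factor PAXX and had the smallest difference in the table, 1.06 ± 1.67 (SE), from scores of 0, 0 and 47.3 with PD-L1 and 0, 4.37 and 0 with IgG. All 10 RNAs of damage signalling kinases and checkpoint were higher, with a median of 3.78, such as the ATR activator ETAA1 (40.3 ± 3.32, at 0 with IgG), ATR and the kinase CHEK2 (24.2 ± 6.61, at 0 with IgG). All 7 nucleotide excision repair RNAs (median 3.23), 4 of 5 base excision and single-strand break repair RNAs (median 3.05) and all 7 mismatch repair RNAs (median 3.65) were higher, including ERCC5, NEIL3 and PMS1. With rescaled libraries ATR (log2 difference 2.69, adjusted p = 0.273 in limma), ERCC5 (2.00, 0.388), NEIL3 (3.47, 0.0799) and PMS1 (1.62, 0.422) did not pass, nor did ATR (0.0673), ERCC5 (0.082) and PMS1 (0.0787) with a pseudocount of 0.01, at larger differences. Adjusted over the list alone, the counts of all these lists were equal to those over all RNAs. The gap polymerase RNA POLB did not pass (log2 difference 3.05 ± 1.35), but did without PD-L1 repeat 3 (4.59, adjusted p = 0.00341 in limma) and with scores of 0 set to the smallest listed score (3.24, 0.0446), in a range of adjusted p to 0.852 with rescaled libraries. Differences of these last 5 lists from the other RNAs were 0.22, 0.32, -0.26, -0.24 and -0.03, with adjusted permutation p-values from 0.721 to 0.937. With a library left out, end joining ranged from 0.11 to 0.30 and the kinase list from 0.12 to 0.56. End joining was at 0.89 with a pseudocount of 0.01 and at 0.043 with scores of 0 set to the smallest listed score. The mismatch repair median lay above that of the table, while its mean lay below that of the other RNAs. That of the kinase list was negative with rescaled libraries (-0.25).

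**Figure D3:**
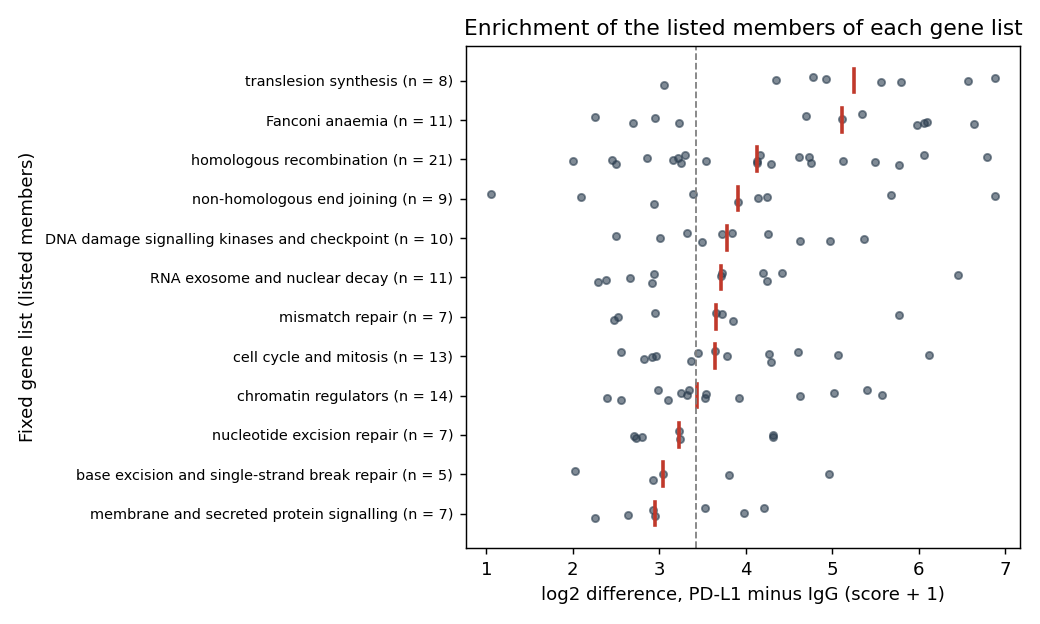
Log2 difference, PD-L1 minus IgG on the log2(score + 1) scale, of each listed member (points) of the 12 fixed gene lists with 5 or more members in the table, with the list median in red and the median of all listed RNAs, 3.42, as a dashed line. The exosome list is drawn as fixed, with MPP6. Translesion synthesis (median 5.25) and Fanconi anaemia (5.11) stand furthest to the right, and their differences from the other RNAs kept their sign with rescaled libraries.

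Outside DNA repair, CD274, which encodes PD-L1 itself, was in the table with scores of 10.5, 26.5 and 23.4 against 0, 2.83 and 4.63 with IgG. Its log2 difference of 2.83 ± 0.74 (SE) had an adjusted p of 0.0102 in limma and fell to 0.66 with rescaled libraries (adjusted p = 0.726 in limma). It also did not pass without PD-L1 repeat 3 (2.68, adjusted p = 0.0536 in limma) or, at larger differences, with pseudocounts of 0.1 (4.07, 0.0529) and 0.01 (5.20, 0.109), and the lowest adjusted p over all alternatives was 0.0012. It was the only 1 of 14 immune checkpoint genes and PD-L1 partners listed. RNA exosome and nuclear decay had 10 of 23 genes in the table, all higher (median 3.33), such as the exonuclease RNA XRN1 (279 ± 129.8 against 0, 2.83 and 5.40) and the exosome nuclease DIS3 (72.8 ± 17.9 against 2.82 ± 0.50). The list as fixed, with 11 of 24 and a median of 3.71, also counted MPP6, a membrane scaffold gene that shares its symbol with an alias of the exosome factor MPHOSPH6. Cell cycle and mitosis had 13 of 36 (median 3.64), all higher, such as the cohesin acetyltransferase ESCO1 (68.9 ± 12, at 0 with IgG), CCNE2 and STAG1. Chromatin regulators had 14 of 35 (median 3.44), all higher, such as CHD9 (133 ± 23.6 against 2.57 ± 2.57), ARID4A and CHD7. With rescaled libraries the log2 differences of XRN1 (4.21, adjusted p = 0.0648 in limma), DIS3 (1.01, 0.189), STAG1 (2.05, 0.327), CHD9 (2.95, 0.213), ARID4A (3.90, 0.0538) and CHD7 (2.81, 0.161) did not pass. The mean of the exosome list differed from the other RNAs by -0.04 without MPP6 and by 0.04 as fixed, with an adjusted permutation p of 0.937 either way. Means of the cell cycle and chromatin lists lay 0.24 and 0.16 above the other RNAs, with an adjusted permutation p of 0.721 for both, and below them with rescaled libraries (-0.24 and -0.88). With a library left out they lay 0.18 to 0.37 and 0.032 to 0.34 above. With scores of 0 set to the smallest listed score they lay 0.40 and 0.65 above (adjusted permutation p = 0.237 and 0.0527), and the exosome list as fixed 0.60 (0.0977).

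Membrane and secreted protein signalling had 7 of 23 genes in the table, all higher (median 2.95), such as the cytokine RNA LIF (34.3 ± 10.8 against 0, 5.40 and 0) and the Wnt coreceptor LRP6 (10.6 ± 0.675, at 0 with IgG). The mean of this list differed from the other RNAs by -0.38 (adjusted permutation p = 0.721), from -0.73 without IgG repeat 1 to -0.087 without IgG repeat 2. With pseudocounts of 0.1 and 0.01 the difference was -0.84 and -1.31, also without passing. Interferon response and antigen presentation had 4 of 28, of which 3 were higher, such as the kinase JAK2 (21.5 ± 13.7, at 0 with IgG) and the RNA sensor IFIH1 (22.9 ± 1.42 against 0, 0 and 3.34). With rescaled libraries LIF (log2 difference 2.68, adjusted p = 0.237 in limma) and IFIH1 (2.38, 0.217) did not pass. Mesenchymal breast cancer cell markers had 4 of 22, all higher, such as the kinase BRAF (41.4 ± 7.09) and the tumour suppressor NF2 (15.7 ± 7.75), both at 0 with IgG. Of 14 epithelial cell markers the tight junction gene CLDN4, named outside the rule, was listed, with a log2 difference of 2.76. Its scores of 13.1, 5.80 and 33.3 with PD-L1 overlapped those of 0, 9.51 and 0 with IgG. The table held 0 of 52 cytosolic ribosomal protein genes, 0 of 27 oxidative phosphorylation genes, 0 of 19 histone genes, 0 of 25 nuclear and small non-coding RNAs, 0 of 13 immune cell markers and 0 of 16 neuronal and muscle markers. Adjusted over the list alone, the counts of these lists and of the exosome, cell cycle and chromatin lists were equal to those over all RNAs. Since the background of RNAs that failed the authors' criterion was not analysed here, these counts are not a test of depletion.

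The authors' deposited table of GO terms holds 47 entries, 33 over-represented and 14 under-represented among the listed RNAs. In the authors' deposited table cellular metabolic process had the smallest p-value (1735 of 8846 genes, fold 1.32, p = 9.4e-47), followed by under-representation of detection of chemical stimulus in sensory perception (1 of 467 genes, fold below 0.2, p = 1.6e-25) and of G-protein coupled receptor signalling (59 of 1194, fold 0.33, p = 2.44e-22). Over-represented in the authors' deposited table were gene expression (791 of 3719, fold 1.43, p = 2.45e-22), cellular protein modification (664 of 3003, fold 1.48, p = 9.47e-22) and organelle organization (675 of 3079, fold 1.47, p = 2.87e-21). Nucleic acid-templated transcription (582 of 2576, fold 1.52, p = 2.13e-20) and cellular biosynthetic process (937 of 4676, fold 1.34, p = 1.36e-19) came next in the authors' deposited table. The list of 10 ended in the authors' deposited table with under-representation of sensory perception of smell (5 of 453, fold below 0.2, p = 2.63e-19) and over-representation of DNA repair (157 of 489, fold 2.15, p = 2.59e-14). Cellular response to DNA damage stimulus held 207 of 729 genes in the authors' deposited table (fold 1.9, p = 5.89e-14). The background behind these folds is not given in the sources used here. It may include genes that this line does not express, so the folds cannot tell association with PD-L1 apart from expression in the cells.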

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

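A score of 0 set to the smallest listed score, matching on exon number, the exosome list without MPP6 and the pseudocount of 1 in the 5-fold count were chosen after the data were seen. The 3152 RNAs at 5-fold became 1101 with libraries rescaled to equal sums and 1660 when the lowest PD-L1 score had to be 5-fold above the highest IgG score, and 2740 to 3064 with a library left out. They stayed within 1.5 times under the other settings, down to 2129 at 10-fold. The 3078 RNAs higher in limma became 990 with rescaled libraries, 2730 to 3032 with a library left out and 2298 to 3096 otherwise. In 1 of the 10 splits of the 6 libraries, the real one, as many RNAs passed, and the highest other split gave 0. The RNAs were selected under the real split, so this outcome was set in advance and says nothing about chance. Besides, 10 splits are too few for a share under 0.05. The median log2 difference of 3.42 became 5.39 and 7.15 with pseudocounts of 0.1 and 0.01, 1.76 rescaled, 2.94 with scores of 0 at the smallest listed score, and 3.18 to 3.61 with a library left out. Pseudocounts act most on scores of 0. Rescaling keeps 0 at 0, so FGL2, at 0 with IgG, fell less (7.57 to 6.73) than TRIO (2.69 to -0.91). Deviations of same-numbered libraries correlated at -0.121, 0.071 and -0.079, and not every library correlated best with its own number. PD-L1 repeats 1 and 2 gave much the same values, -0.121 and -0.112 with IgG repeat 1 and 0.057 and 0.071 with IgG repeat 2. The check could hardly separate these repeats, so whether the repeat numbers mark paired samples stays open. With the repeat number as a block 3091 RNAs were higher, and no call of a named RNA changed. The block leaves each log2 difference as it was, so the list tests and the 5-fold count could not change. A minimum mean PD-L1 score of 1 kept all 3152 RNAs, so it could not change any result. The number of gene lists past the threshold, 2, became 0 with a pseudocount of 0.01, at larger differences and a larger SD over RNAs, and was 2 to 3 with a library left out, homologous recombination passing without PD-L1 repeat 3. The difference of 0.14 for the authors' DNA damage genes turned to -0.084 and -0.33 with pseudocounts of 0.1 and 0.01 and -0.058 rescaled, passed at 0.24 with scores of 0 at the smallest listed score, and was 0.097 to 0.19 with a library left out. The cause was not tested.

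Some lists that did not pass changed sign, and here too the cause was not tested. With pseudocounts of 0.1 and 0.01 and rescaled libraries, differences from the other RNAs were -0.27, -0.90 and -0.25 for damage kinases, -0.93, -2.05 and -0.78 for the exosome, -0.22, -0.68 and -0.24 for cell cycle, and -0.95, -2.13 and -0.88 for chromatin, but with scores of 0 at the smallest listed score 0.58, 0.60, 0.40 and 0.65 for these lists in turn (adjusted permutation p = 0.127, 0.0977, 0.237 and 0.0527). Matched on PD-L1 score they were -0.17 for the exosome and -0.079 for chromatin, and matched on exon number -0.035 for cell cycle and -0.20 for chromatin. Without MPP6, a gene of another function, the exosome list was at -0.042. As fixed, it had 0 of 11 RNAs at 0 in all 3 IgG libraries, and the chromatin list 0 of 14. In the damage kinase and cell cycle lists these were 2 of 10 and 4 of 13. A smaller pseudocount raises RNAs at 0 with IgG most, so scores of 0 may contribute to the changes in the exosome and chromatin lists. Mismatch repair was at 0.16 with scores of 0 at the smallest listed score and 0.23 by medians. With a library left out mismatch repair ranged from -0.15 to 0.20, base excision repair from -0.49 to 0.10 and the exosome from -0.021 to 0.099. Among the 57 named RNAs rescaling turned POLB (-0.30), ARHGAP29 (-0.34), ARHGEF28 (-0.71), CEP95 (-0.83) and TRIO (-0.91), and leaving out PD-L1 repeat 3 turned C9orf142 (-0.81, in a range to 1.99 without PD-L1 repeat 1). Rescaling ended 25 of the 55 named calls, pseudocounts of 0.1 and 0.01 ended 3 and 9, and leaving out PD-L1 repeat 1, 2 or 3 ended 3, 3 and 2, and leaving out IgG repeat 1 ended 1. Sequencing depth is unknown, so how far it limits low scores cannot be stated.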

Other observations

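The tests on the score step, on the correlations of repeat 3 and on exon number were chosen after the results were seen, and those on zinc finger genes were chosen from the table as well. Genes encoding zinc finger proteins, many of them DNA-binding repressors, made up 161 of the listed RNAs by their ZNF symbols, and 153 of these were higher with PD-L1 in limma with Benjamini-Hochberg adjustment. The largest differences belonged to ZNF280D (59.9 ± 10.6 with PD-L1), ZNF215 (56.8 ± 16.9), ZNF236 (55.5 ± 18.0) and ZNF33A (50.5 ± 9.54), all at 0 in the 3 IgG libraries, and ZNF800 (90.8 ± 3.84 against 0, 7.46 and 0). In all, 97 (60.2%) were at 0 in all 3 IgG libraries against 30.2% of the other RNAs. How their mean log2 difference compared with that of the other RNAs changed sign with the treatment of scores of 0 and with the scaling. It was -0.17 as fitted (permutation test, p = 0.0404), -0.57 with scores of 0 set to the smallest listed score (permutation p = 1e-05, the smallest these permutations can give), 0.59 with rescaled libraries (permutation p = 6e-05) and 0.63 and 1.52 with pseudocounts of 0.1 and 0.01. Within bins of exon number it was 0.104 (permutation test, p = 0.165), which leaves open whether they stand apart. They had a median of 5 exons against 12.

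Non-coding transcripts were few. The highest scores among them were those of AHSA2, a transcribed pseudogene (499 ± 198 against 22.7 ± 11.3 with IgG), and the long non-coding RNAs HGC6.3 (336 ± 182 against 38.6 ± 22.9) and LOC101927322 (163 ± 82.5 against 6.30 ± 3.81), named after their values were seen. Reads shared with near-identical copies could not be told apart for such genes. Centrosome and cilium terms had the highest folds in the authors' deposited table, with centrosome duplication at 21 of 31 genes (fold 4.54, p = 0.000181), microtubule organizing center organization at 37 of 86 (fold 2.89, p = 0.000225) and ciliary basal body docking at 41 of 96 (fold 2.86, p = 5.05e-05). Epidermal cell differentiation stood 2 times in the authors' deposited table, with 16 of 310 genes at fold 0.35 and with 51 of 310 at fold 0.53. The folds imply an expected share of 14.7% for the first and 31.0% for the other. The other terms lie between 14.8% and 15%, apart from those whose fold is given only as a limit.

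The first pattern is the lower PD-L1 repeat 3. If a step between low scores is the score of 1 read, a smaller library would give a larger step, and it was 0.177 against 0.202 and 0.181 in repeats 1 and 2, but the scale of the scores is not given in the sources used here and a smaller library stays open. An IgG library under its label is argued against by a Spearman correlation of 0.741 or more with the other PD-L1 repeats, above its highest value of 0.594 with an IgG library. Median log2 ratios of repeat 3 to the mean of repeats 1 and 2 were 0.03 in RNAs with 1 to 5 exons and -0.91 in those with over 20, and at fixed score in repeats 1 and 2 the partial rank correlation of its score with exon number was -0.128 (permutation p = 0.0001, the smallest 10000 permutations can give), so fewer scored peaks per RNA may contribute, weakly. Its smallest score of 21 steps against 10, and a second decimal in 39.5% of its scores of 10 or more against 84.8% and 85.2%, leave other peak calling or rounding by the authors open, and no biological explanation was tested.

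The second pattern is that translesion synthesis and Fanconi anaemia RNAs lay above the other listed RNAs. Exon number as the whole cause is argued against by the differences within bins of exon number, 1.46 and 0.93 (adjusted permutation p = 0.00312 and 0.0162). A single leading gene is argued against by the highest unadjusted permutation p with any 1 member left out, 0.00835, without FANCL. POLQ and BRIP1 also stand on other repair lists, and with a pseudocount of 0.01 the differences grew to 2.67 and 1.98 without passing, as the SD over all listed RNAs grew from 1.02 to 3.07. That RNAs of these pathways associate more strongly with PD-L1 is a hypothesis from the same libraries, which the abundance of these RNAs in the cells, not analysed here, leaves open.

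The last pattern is that enrichment followed gene structure, with a Spearman correlation of 0.226 across RNAs between log2 difference and exon number (permutation p = 1e-05, the smallest these permutations can give), and of 0.344 with scores of 0 set to the smallest listed score. Exon number correlated at 0.385 with the mean PD-L1 score and at 0.183 with the mean IgG score. Median log2 differences were 3.13, 3.27, 3.50 and 3.83 in RNAs with 1 to 5, 6 to 10, 11 to 20 and over 20 exons. In these groups the median PD-L1 scores were 17.7, 23.1, 34.9 and 69.5, and 38.8%, 36.3%, 27.8% and 26.8% were at 0 in all 3 IgG libraries. Both treatments of scores of 0 used here understate the change of RNAs with low scores. The trend therefore cannot be told apart from score level, and it was not computed with smaller pseudocounts or rescaled libraries. The other 3 properties tested gave 0.172 for genomic span, 0.089 for transcript length (0.152 with scores of 0 at the smallest listed score) and -0.156 for GC content, all 4 keeping this p after Benjamini-Hochberg adjustment, and listed RNAs had a median of 12 exons and a GC content of 43.4%, against 7 exons and 50.8% in 16148 other coding genes, which include genes this line does not express. The authors' DNA damage genes differed from the other RNAs by 0.047 within bins of exon number (permutation p = 0.521) and by 0.058 within bins of mean PD-L1 score (permutation p = 0.427), against 0.14 without bins. Exon number is therefore a candidate explanation for the small difference, which had not passed the threshold. The PD-L1 score is part of the log2 difference itself, so matching on it cannot point to a cause.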
